A study of Mus musculus with 8 samples.

How the data were processed

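Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The material was 8 libraries of mouse naive CD4 T cells from spleen. Per the labels' protocols, the sorted cells were activated with antibodies to CD3 and CD28 and 20 ng/mL TGF-β, with or without 100 U of IL-2, harvested at 48 h and tagmented at 90000 cells per sample. Cells were labelled as control or as conditional double knockout of Tet1 and Tet3 (cDKO). Each of the 4 groups held 2 libraries. The design text calls the replicates biological. Which animals they came from is not given in the sources used here, so permutation p-values measure only the spread between these libraries. Fisher's exact tests below take regions as units and treat them as independent. Their p-values do not measure the spread between libraries.

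The authors deposited 1 peak list per library. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.4.1, Picard, SAMtools 1.3.1, MACS2 2.2.7.1, DiffBind 2.10.0, ChIPseeker 1.18.0 and HOMER 4.11.1 with the mouse build GRCm38 (mm10), with no role or order. Settings for read shifting, duplicates and peak calling are not given in the sources used here. Each deposited peak has a position, a summit, a fold over background (a ratio) and a −log10 p-value and −log10 q-value, all of them the authors' own values for that peak. The deposited score column was not used. The largest q-value listed was 0.05 in each deposited list, to rounding. For regions, these values served only to rank or filter peaks within a list, and no test compared a region's values between libraries.

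Read depth is not stated in the lists. Fold and −log10 p together resolved to a whole-number summit pileup (tolerance 0.001 in −log10 p) for at least 99.98% of every 10th peak in each list, which gave a background pileup per library. Division by the shortest peak of the list gave an implied background density in reads per kb. This assumes that the shortest peak equals the fragment length used in calling, so the density is only a rough guide to depth and enters no test of regions.

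Peaks of all 8 lists were merged where they overlapped by at least 1 bp, which gave 175276 union regions with a median width of 250 bp. Because list length differed between libraries, the main analysis used equal-number lists: the 65811 peaks of highest −log10 p in each library, the length of the shortest list. A region was called higher on one side of a comparison when every library of that side listed it and no library of the other side did. "Higher" and "lower" below have that meaning, and a lower region can still hold a weaker peak further down a deposited list. Genotype and IL-2 were each compared with 4 libraries per side, and each was repeated within the arms of the other with 2 per side. Every split of the same libraries into sides of equal size was counted, 35 for 4 against 4 and 3 for 2 against 2. A share under 0.05 cannot be reached with 3 splits, where the smallest is 0.333. Similarity of 2 libraries was the Jaccard index of their regions. Values per library were compared with exact 2-sided permutation tests over 70 relabellings, whose smallest p is 0.0286.

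No genome sequence was given, so the planned motif, GC and CpG comparisons were not run. Genes came from the RefSeq gene table of GRCm38.p6, which gives gene bodies without strand or exons. In place of the planned nearest transcription start, a region was assigned to the protein-coding gene whose body held its midpoint (the smallest, if several). Otherwise the nearest gene body within 100 kb was taken. Promoters were replaced by gene ends, within 1 kb of either end of a protein-coding gene. Whether a region is exonic, intronic or untranslated was therefore not analysed here. Of 271 genes in 16 lists fixed before the data were examined, 269 matched the table. Each list was tested with Fisher's exact test, per direction, against the 64597 regions listed in at least 4 libraries, with Benjamini-Hochberg adjustment over the 16 lists. That background includes 40694 regions listed in all 8 libraries, which no call can take. Tests were therefore repeated among the 6158 regions listed in exactly 4 libraries, the ones that could have been called, a choice made after seeing the data. The lists were Treg, IL-2 and STAT5, TGF-beta and SMAD, Th1 and cytotoxic, Th2, Th17, Tfh, naive and memory, TCR-induced activation, glucose and amino acid metabolism, DNA methylation, germline, B cell, CD8 and NK cell, myeloid and dendritic cell, and erythroid.

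Named regions followed a rule fixed before the data were examined. Tet1, Tet3, Foxp3, Il2ra and Il2 are described in every library. For genotype and IL-2 the rule takes, per direction, up to 10 regions called by both equal-number and deposited lists, by the smallest worst rank, and up to 4 genes per gene list. For comparisons of 2 against 2 libraries it takes up to 5 regions per direction. For some lists, genes with called regions are named beyond those 4. Other regions named outside the rule are said to be so. A few regions that the rule takes are not reported here.

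The calling step was tested on simulated lists of all 175276 regions with the real background pileups, 200 of them changed, under 4 combinations of region strength and added noise. For the genotype comparison, between 17.5% and 39.5% of regions changed 4-fold were recovered, and between 1% and 7% of those changed 2-fold, none in the wrong direction. The simulated replicates were less alike (Jaccard index at most 0.582) than the real ones, so these rates are not calibrated to the data. For genotype without IL-2, with 2 libraries per side, recovery was 34% to 60.5% at 4-fold and 13.5% to 22.5% at 2-fold, with at most 1 call in the wrong direction. The simulation called between 241 and 449 unchanged regions with 4 libraries per side and between 5743 and 10451 with 2, and chance levels below were therefore taken from splits of the real libraries. Alternatives tried were deposited lists in full, N halved (shorter equal-number lists), a −log10 q of at least 5, summit windows of 250 bp, autosomes, a looser call, other gene assignments and leaving out each library. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.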

Results

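Accessible regions were mapped in activated CD4 T cells under conditions that induce regulatory T cells, with and without Tet1 and Tet3, which encode enzymes that oxidise methylated cytosine in DNA. The design asks how loss of both enzymes changes open chromatin during differentiation with TGF-β, and whether added IL-2, a growth factor for regulatory T cells, changes that. The 8 deposited lists held 835203 peaks. Control libraries without IL-2 held 145979 and 92488 peaks, and cDKO libraries without IL-2 held 96764 and 108842. With IL-2, the control libraries held 113317 and 65811 peaks and the cDKO libraries 96752 and 115250.

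Longer lists had a higher implied background density, from 4.94 reads per kb in replicate 2 of control plus IL-2, the shortest list, to 9.50 in replicate 1 of control without IL-2, the longest. Across the 8 libraries the exact permutation test gave Pearson's r = 0.919 (p = 0.00102) and Spearman's rho = 0.952 (p = 0.00114). This does not show that depth set peak number, because the density is divided by the shortest peak of the same list (90 to 154 bp). With the background pileup alone r was 0.471 (exact permutation p = 0.238) and rho 0.595 (exact permutation p = 0.132). Peak number did not differ detectably between genotypes (exact permutation p = 0.8, n = 4 per side) or with IL-2 (exact permutation p = 0.514, n = 4 per side). Both had an adjusted p of 0.8 over 8 tests of library values.

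**Figure D1:**
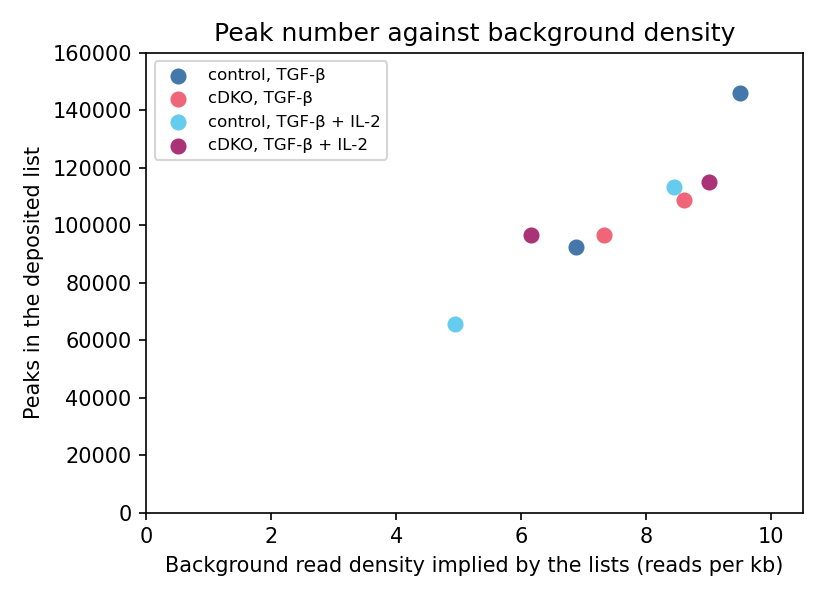
Peaks in each deposited list (vertical axis) against the background read density implied by that list (horizontal axis, reads per kb), 1 point per library, coloured by group. The list of 65811 peaks lies at 4.94 reads per kb and the list of 145979 at 9.50.

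The targeted genes were examined first. Tet1 (chromosome 10, 62804570 to 62887469, GRCm38) was assigned 7 to 9 regions in the control equal-number lists and 6 to 9 in the cDKO lists. Inside the gene there were 6 to 8 and 5 to 8. Tet3 (chromosome 6, 83362373 to 83457208) held 10 to 12 in control and 11 in every cDKO library. The deleted exons are not given in the labels, so regions elsewhere in the genes do not check the deletion. One region inside Tet3, from 83421630 to 83422134, was in the equal-number lists of all 4 cDKO libraries and of no control library, though 3 control deposited lists held it at lower rank.

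Foxp3, the lineage factor of regulatory T cells, was assigned 1 or 2 regions in every equal-number list, with 0 to 2 inside the gene. The region within the gene from 7586226 to 7586968 on chromosome X was listed in 7 of 8 libraries, all except replicate 2 of control plus IL-2. Il2ra, which encodes the high-affinity IL-2 receptor chain, was assigned 14 to 16 regions, of which 7 to 10 lay inside the gene. Il2 was assigned 6 to 8, of which 0 or 1 lay inside it. A region at the boundary of the Il2 gene with the higher coordinate (chromosome 3, 37125756 to 37126075) was listed in both control libraries without IL-2 and in no other equal-number list. In the deposited lists it also appeared, at lower rank, in both cDKO libraries without IL-2, and in none of the 4 libraries with IL-2. A region 45.4 kb from Il2 (37171000 to 37171772) was in the equal-number lists of all 4 control libraries and of no cDKO library, though 2 cDKO deposited lists held it at lower rank.

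**Figure D2:**
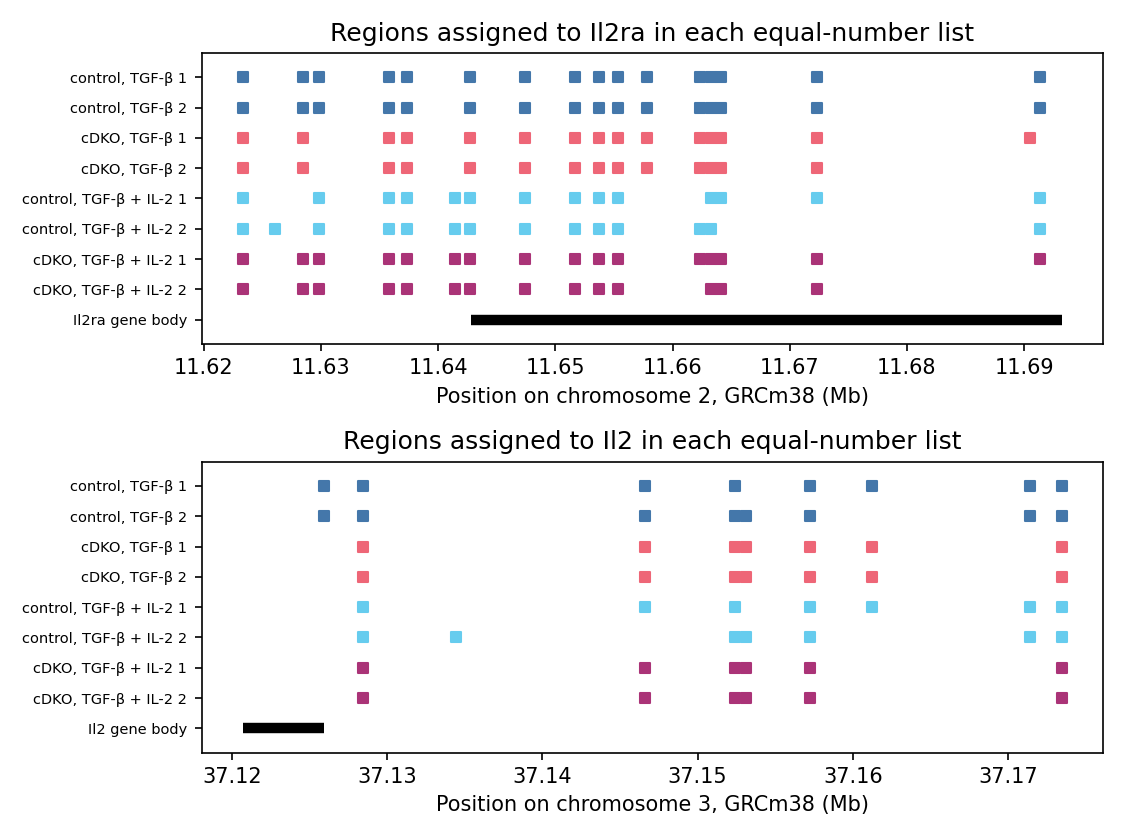
Regions assigned to Il2ra (upper panel) and Il2 (lower panel) that are present in each equal-number list, drawn as a square at the midpoint, not to width, against position in Mb on GRCm38. Each row is 1 library, and the black bar is the gene body. The Il2 region at 37125756 is marked only in the control libraries without IL-2.

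Libraries of one genotype resembled each other more than those of different genotypes. The mean Jaccard index was 0.761 between replicates (n = 4 pairs), 0.730 between IL-2 arms of one genotype and 0.698 between genotypes in one IL-2 arm (n = 8 pairs each). It was 0.677 where both differed. For genotype, the index within sides exceeded that between sides by 0.0530, and no other split of the 8 libraries gave as large a value (exact permutation p = 0.0286 over 35 splits). With deposited lists the excess was 0.0277 (exact permutation p = 0.0571). For IL-2 the excess was 0.0155 (exact permutation p = 0.114).

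**Figure D3:**
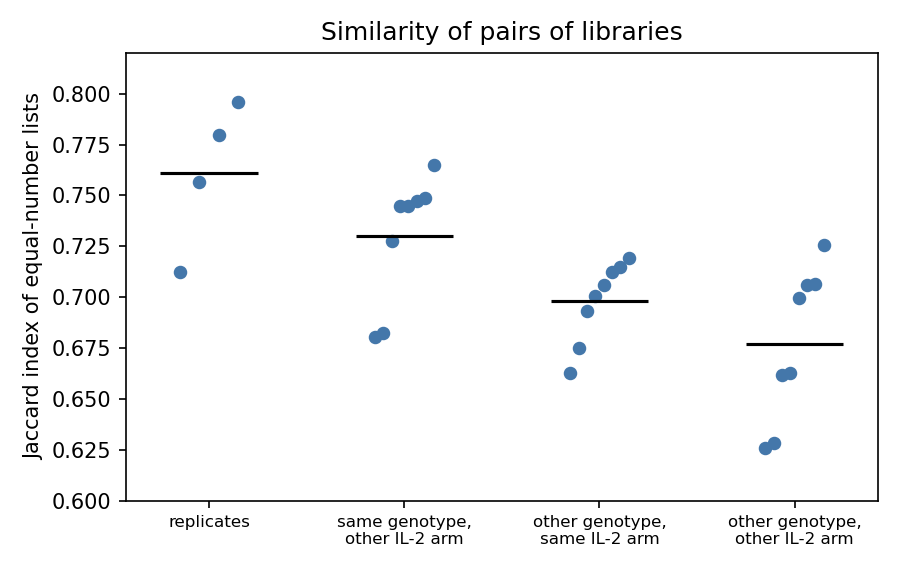
Jaccard index of equal-number lists (vertical axis, from 0.6) for each of the 28 pairs of libraries, grouped by what the pair shares. Points are pairs and lines are means, which fall from 0.761 for replicates to 0.677 for pairs that share neither genotype nor IL-2.

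Regions at genes of naive and memory T cells were called in both directions for genotype, and the one list result that passed rests on the setting. Of 346 background regions at such genes, 15 were lower in cDKO, at Bach2, Ets1, Foxo1, Foxp1, Il7r, Itga6, Lef1, Satb1 and Tcf7 (odds ratio 2.71, Fisher's exact test, adjusted p = 0.0126 over 16 lists, 4 libraries against 4). Tcf7 and Lef1 encode transcription factors of naive and memory T cells, and Il7r a cytokine receptor that supports their survival. The list also had 8 regions higher in cDKO (odds ratio 2.25, Fisher's exact test, p = 0.0308, adjusted p = 0.246), and Bach2, Foxo1, Itga6 and Lef1 had regions in both directions. Lower examples were a region in Satb1 (chromosome 17, 51779990 to 51780251), a region in Bach2 (chromosome 4, 32391292 to 32391622) and a region 10.9 kb from Tcf7 (chromosome 11, 52294132 to 52294423). Against only the regions that could have been called, 15 of 43 were lower, with an odds ratio of 2.56 and an adjusted p of 0.113 (Fisher's exact test, a background chosen after seeing the data). The call was also lost with deposited lists (6 of 516, odds ratio 2.27, adjusted p = 0.527, Fisher's exact test). Without chromosome 6, 11 of 285 were lower (odds ratio 2.42, adjusted p = 0.128), and under the looser call 33 of 375 (odds ratio 1.33, adjusted p = 0.626), both chosen after seeing the data (Fisher's exact test). It was lost as well without replicate 2 of control without IL-2 (odds ratio 1.86, adjusted p = 0.221), of cDKO without IL-2 (2.29, 0.0766) or of cDKO plus IL-2 (1.90, 0.286, Fisher's exact test). The call held with genes assigned by gene body plus 10 kb (15 of 238, odds ratio 4.02, adjusted p = 0.000206, Fisher's exact test). It also held against all listed regions (15 of 517, odds ratio 2.66, adjusted p = 0.014, Fisher's exact test). Both of these backgrounds include regions that no call can take.

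No other list passed for genotype. The TGF-beta and SMAD list had 8 of 224 regions lower in cDKO (adjusted p = 0.277, Fisher's exact test), at Ldlrad4, Ski, Smad3, Smurf2, Tgfbr2 and Tgfbr3, and 2 higher, at Klf10 and Ldlrad4. The lower ones include both a receptor and a signal transducer of TGF-β. With deposited lists this list showed no excess, as 1 of 321 regions was lower (odds ratio 0.6). The Treg list had 1 region lower, 53.4 kb from Nt5e, and 1 higher, 22.3 kb from Lrrc32. The IL-2 and STAT5 list had 4 lower, at Bcl2, Il2, Jak1 and Stat5b, and 4 higher, at Jak1, Lif and Stat5b (Fisher's exact test, adjusted p = 0.984 and 0.747). Except for Th1, genes of other helper fates went both ways. Th1 genes had 3 regions higher (Eomes, Fasl and Il12rb1) and 0 lower. Th2 genes had 1 higher (Gfi1) and 2 lower (Gata3 and Il4ra), Th17 genes 2 higher (Il22 and Il6st) and 4 lower (Il1r1, Il6st, Rbpj and Stat3), and Tfh genes 2 higher (Bcl6 and Slamf6) and 1 lower (Il21). Lower regions at activation genes lay at Batf3, Fos, Irf4 and Nfatc1 (Fisher's exact test, adjusted p = 0.830), and 1 higher region lay near Jund. In the DNA methylation list, regions in Dnmt1 and Uhrf2 were lower and regions in Tet2 and Tet3 higher. Of the lists of other cell types, the erythroid list had 2 of 14 regions higher (adjusted p = 0.147, Fisher's exact test). The Th1, Th2, Th17, Tfh, metabolism, DNA methylation, germline, B cell, CD8 and NK cell, and myeloid lists had 0 to 4 called regions per direction (Fisher's exact test, adjusted p = 0.781 or more).

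The share of a list's regions present per library gave no call either. Relative to all regions, Th1 and cytotoxic genes stood 6.67 percentage points above control in cDKO, and CD8 and NK cell genes 7.08 points above. The Tfh difference was -3.63 points and that of glucose and amino acid metabolism -4.35 points. Each reached the smallest p that the exact permutation test allows, 0.0286 (n = 4 per side), with an adjusted p of 0.114.

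In all, 677 regions were higher and 1073 lower in cDKO than in control. Those called by both kinds of list numbered 29 higher and 131 lower. The strongest higher region lay 17.2 kb from Bcat1, which encodes a branched-chain aminotransferase (chromosome 6, 145093014 to 145093770). It ranked 11043 or better in all 4 cDKO libraries and was in no control list of any length. Others lay in Pde6h (chromosome 6, 136953831 to 136954508), 69.9 kb from the histamine receptor gene Hrh1 (chromosome 6, 114553099 to 114553348), in Epb41l1 and in Ganc. The strongest lower regions lay 21 kb from Med21 (chromosome 6, 146671361 to 146671917), 22.3 kb from Stk38l (chromosome 6, 146702238 to 146702933), and in Tm7sf3, Lrmp, Gtdc1 and Galnt10. Of the 160 regions called by both kinds of list, 39 (24.4%) lay on chromosome 6. Among all genotype calls the share was smaller, with 85 of the 677 higher and 71 of the 1073 lower regions there.

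The largest number from any other split was 554. With deposited lists the split was 516 higher and 507 lower, against 38.7% higher in the main lists, and another split gave 1059. Shorter equal-number lists (N halved) gave 405 higher and 571 lower.

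**Figure D4:**
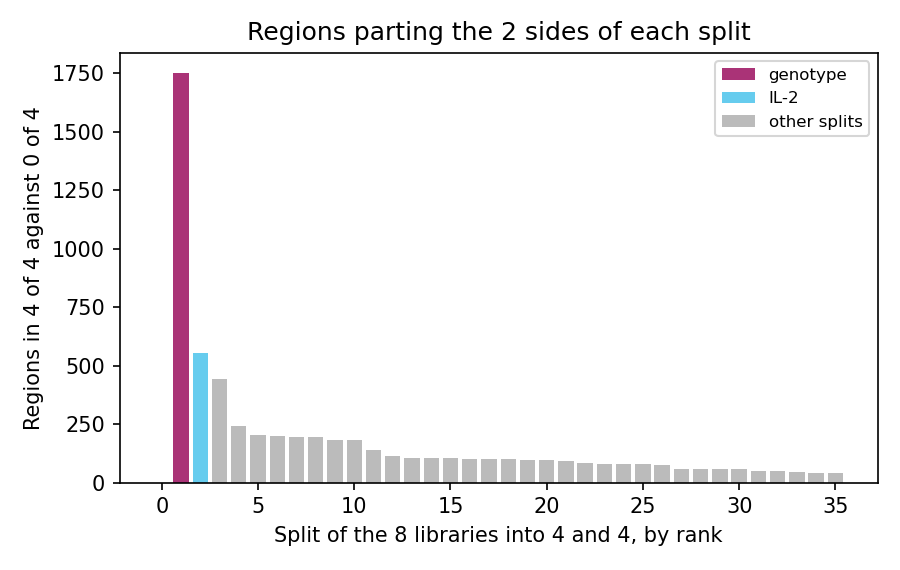
Number of regions listed in all 4 libraries of one side and none of the other (vertical axis), for each of the 35 splits of the 8 libraries, ordered by that number (horizontal axis). The genotype split has 1750 regions and the IL-2 split 554, and grey bars are the other splits.

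**Figure D5:**
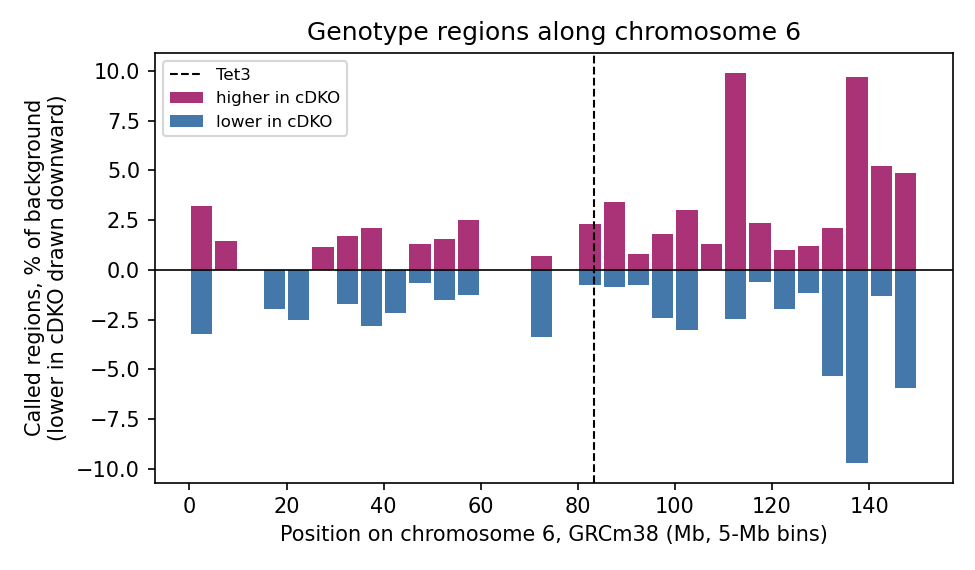
Percentage of background regions higher in cDKO (upward) and lower in cDKO (downward) in bins of 5 Mb along chromosome 6, with the position of Tet3 dashed. The bin from 135 to 140 Mb holds 10 higher and 10 lower regions of 103.

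Gene ends were compared among the 6158 regions that could have been called, those listed in exactly 4 libraries, a background chosen after seeing the data. Of regions lower in cDKO 3.26% lay at a gene end, against 6.92% of the rest (odds ratio 0.453, Fisher's exact test, adjusted p = 8.52e-06 over 4 tests). Of regions higher in cDKO 6.94% did, against 6.20% (Fisher's exact test, adjusted p = 0.450). For IL-2 the shares were 4.49% of higher and 3.64% of lower regions (Fisher's exact test, adjusted p = 0.268 and 0.236). The planned background gave 19.1% to 19.3% for the rest and put all 4 shares below it, but it holds regions present in all 8 libraries, which cannot be called and had 26.1% at gene ends.

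Within the arm without IL-2, 3702 regions were higher and 4021 lower in cDKO, and the other splits gave at most 2056. The strongest higher ones lay near Bcat1 and Hrh1 and in Fbln1, Pde6h and Pdzrn3, all but Fbln1 on chromosome 6. Strong lower ones lay in Ncam2 and Auh, and near Med21 and Otud7a. With IL-2, 3461 were higher and 3808 lower, and the other splits gave at most 2549. Higher regions lay in Eps8 (chromosome 6, 137541325 to 137541959), Blk and Etv6. Lower ones lay in Gtdc1, Klra5 and another part of Etv6. N halved gave 1909 higher and 2065 lower without IL-2, and 1891 and 2024 with it. Deposited lists gave 2671 higher and 6835 lower without IL-2. With IL-2 the direction turned in deposited lists, to 6350 higher and 1633 lower, and a mixed split of that arm then gave 10115 regions. With 2 libraries per side, 3 splits allow no share under 0.333.

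The 2 arms use different libraries. Regions going the same way in both numbered 1750, which are the genotype calls over 8 libraries, against 293.3 for independent lists, a ratio of 5.97. Independence is too low a mark, since splits that mix genotypes within both arms gave ratios of 1.55 to 3.78. Opposite directions were found at 40 regions.

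Fewer regions differed with IL-2 than with genotype. Over both genotypes 334 were higher and 220 lower with IL-2. Il2ra had one of each: a region 1.33 kb outside the gene (chromosome 2, 11641332 to 11641586) was higher, and a region inside it (11657724 to 11658003) was lower. The Treg list had 4 of 192 regions lower with IL-2, at Icos, Il2ra, Itgae and Nt5e (odds ratio 6.32, adjusted p = 0.0698, Fisher's exact test), and 1 higher. Against only the regions that could have been called, 4 of 13 were lower (odds ratio 12.2, adjusted p = 0.0141, Fisher's exact test), a background chosen after seeing the data. The excess was not stable: with deposited lists 1 of 262 was lower (odds ratio 0.96, adjusted p = 1) and under the looser call 8 of 202 (odds ratio 0.97, adjusted p = 1, Fisher's exact test). With gene bodies plus 10 kb the odds ratio was 4.18 (adjusted p = 1, Fisher's exact test). Leaving out each library gave adjusted p-values of 0.0794 to 1 (Fisher's exact test) and odds ratios of 2.46, without replicate 1 of control without IL-2, to 4.74. The background was then redrawn from the remaining libraries and held 196 to 201 Treg regions. The odds ratio fell by over 1.5 times as well without replicate 1 of cDKO without IL-2 (3.82) or of cDKO plus IL-2 (3.68), or replicate 2 of cDKO plus IL-2 (3.61). The TGF-beta and SMAD list had 4 of 224 higher, at Itgb8, Pmepa1 and Ski (Fisher's exact test, adjusted p = 0.474). Single regions were higher near Eomes, Il24 and S1pr1 and in Tet2. Single regions were lower near Cxcr5 and Il1r1 and in Foxp1. Every other list had at most 2 regions per direction (Fisher's exact test, adjusted p = 0.560 or more). The Th2 list stood 4.36 points higher per library with IL-2 (exact permutation p = 0.0286, adjusted p = 0.229, n = 4 per side).

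Among all 35 splits only the genotype split gave more regions than the IL-2 split. The direction did not hold: deposited lists gave 56 higher and 388 lower, and 9 of 35 splits were then as large. With a peak covering 50% of its region, a setting chosen after seeing the data, 249 were higher and 330 lower. Both kinds of list called only 1 region higher, on chromosome 18 (83862967 to 83863204, with no gene within 100 kb), and 1 lower, in Rbm33 (chromosome 5, 28416138 to 28416319). The numbers also rest on single libraries, and without replicate 1 of control without IL-2 there were 732 higher and 571 lower.

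In control cells 2292 regions were higher and 2407 lower with IL-2, and the split by replicate number gave 3693. Higher regions lay in Cd96, Rfx7, Slc22a23 and Man1a. Lower ones lay 7.03 kb from Dnmt3b, a DNA methyltransferase gene (chromosome 2, 153694576 to 153694937), in Tox and near H2-Q10. In cDKO cells 2672 were higher and 2820 lower, and the other splits gave at most 2104. Higher regions lay 2.92 kb from Cd2 (chromosome 3, 101272578 to 101273402) and in Xpo4, Wwp1 and Rad52. Lower ones lay in Fibcd1 and Hdac9. With deposited lists the split was 404 higher and 6193 lower in control, where the split by replicate number, which parts the longer from the shorter lists, gave 16932, and 4059 higher and 3553 lower in cDKO. Regions going the same way in both genotypes numbered 554, the IL-2 calls over 8 libraries against 134.6 for independent lists, where splits that mix the IL-2 arms within both genotypes gave ratios of 1.42 to 2.55. Opposite directions were found at 40.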

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

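The splits for genotype and for IL-2 and all tests of chromosome 6 were chosen only after the result was seen, while the splits for the naive and memory list were set beforehand.

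The genotype regions numbered 1750 with equal-number lists, and 1 of 35 splits, the real one, gave as many (highest other split 554). This argues against chance for these lists, but 0.0286 is the smallest share that 35 splits allow. Most other splits also part replicates of 1 group. With deposited lists 2 of 35 splits, the real one among them, gave as many, so chance is not excluded there. The IL-2 regions numbered 554, and 2 of 35 splits gave as many (the other was genotype, 1750). Genotype is itself a contrast of the design, and the remaining splits gave at most 441. As genotype gave more regions, IL-2 could not reach a share under 0.05. This test therefore cannot exclude chance and decides nothing. For the naive and memory list, 1 of 35 splits gave as small a p, and the other splits put at most 3 regions in that list against 15, but they called at most 334 regions in 1 direction, too few to reach that p at the same odds ratio. The test set beforehand therefore decides nothing, and it does not exclude chance.

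Genotype regions crowded on distal chromosome 6. In a scan of 475 bins of 5 Mb, 3 held more than their share, all on chromosome 6 (110 to 115, 135 to 140 and 145 to 150 Mb), and among regions that could have been called 1 of 92 bins did (135 to 140 Mb). From 110 Mb, a boundary set from these same calls, 89 of 195 regions that could have been called were called (odds ratio 2.17), which describes the excess and tests nothing. The split of the 4 longest from the 4 shortest deposited lists had fewer calls there (odds ratio 0.27, 95% interval 0.111 to 0.659, genotype 5.81), which argues against list length, while with equal-number lists it had 5 of its 104 calls there (2.1, 0.838 to 5.27), too few to exclude depth. Of the 89, 56.2% were higher in cDKO, against 38.7% of all genotype regions. On the planned background the odds ratio was 4.05 (3.02 to 5.43) for higher and 1.89 (1.36 to 2.61) for lower regions. That background holds regions that cannot be called. Among regions that could have been called, 50 of 195 from 110 Mb were higher, against 627 of 5963 elsewhere. Lower were 39 of 195 from 110 Mb, against 1034 of 5963 elsewhere. The shares of lower regions lie close together, so an excess in both directions is not clear. A gain or loss of DNA copies therefore cannot be told apart. A candidate explanation is sequence of another strain carried with an engineered allele. The IL-2 comparison showed no excess among regions listed in 4 libraries and not called for genotype (0.802, interval 0.427 to 1.51). On the planned background it showed none either (0.998, 0.548 to 1.82). For genotype, both IL-2 arms showed an excess on the planned background (1.73, 1.45 to 2.07, and 1.79, 1.502 to 2.13). Among regions that could have been called only the arm with IL-2 did (1.45, 1.13 to 1.86, against 1.22, 0.957 to 1.56). Every genotype region over 8 libraries is also called in each arm. Both arms thus reuse the 89 calls behind the boundary and are not separate evidence. Sequence of another strain therefore cannot be told apart as the source. Tet3 lies on the same chromosome, but strain background is not given in the labels, so an effect of the missing enzymes on these 89 regions cannot be told apart either.

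Opposite genotype directions in the IL-2 arms were seen at 40 regions, which is why they are listed here. The split that tests this difference gave the fewest regions of the 35 splits, so no excess was found. A wide median peak marked replicate 2 of control plus IL-2 (335 bp, others with IL-2 221 to 236 bp). Chromosome Y held 0.0411% of the peaks of replicate 1 of control without IL-2 (other control libraries 0.0334% to 0.0344%). These were 2 of 32 sets of 4 libraries tested for a far value, and chance marks about 1 in 20.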

How the results depend on the processing

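Results without chromosome 6, with a peak covering 50% of its region, with a background of regions listed in exactly 4 libraries, and the gene lists under a looser call or with a library left out were chosen after seeing the data. The planned wording of the 50% rule holds for every peak and moved nothing, so the version run asks for cover of the merged region. Motif alternatives were not run. Over all results, 155 alternatives stayed on the same side or within 1.5 times, 55 moved, 12 were weaker and 4 stronger.

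N halved gave 405 genotype regions higher and 571 lower, 218 higher with IL-2, 1909 and 2065 without IL-2, 1891 and 2024 with it, 1274 and 1253 for IL-2 in control and 1452 and 1489 in cDKO, from shorter lists. Deposited lists gave 507 lower in cDKO, 56 higher and 388 lower with IL-2, 6835 lower without IL-2, 6350 and 1633 with it, 404 and 6193 in control and 4059 higher in cDKO. A −log10 q of at least 5 gave 434 lower in cDKO, 30 and 386 for IL-2, 2375 higher without IL-2, 1264 lower with it, and 292 and 4952 in control. Calls by at least 3 of 4 against at most 1 of 4 gave 4431 and 4839 for genotype and 2748 and 2917 for IL-2, a looser rule. The cause of the changes under deposited lists and the q filter was not tested. Both overlap ratios stayed within 1.5 times of the main one under every alternative run.

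Leaving out each library gave 858 to 1082 regions higher and 1222 to 1617 lower in cDKO, and 396 to 732 higher and 309 to 571 lower with IL-2, since fewer libraries must agree. Regions higher in cDKO moved by over 1.5 times without control replicate 1 (1017) or 2 (1075) lacking IL-2, or cDKO plus IL-2 replicate 1 (1048) or 2 (1082), and lower regions without control plus IL-2 replicate 2 (1617). For IL-2, without control replicate 1 lacking IL-2 there were 732 and 571, without control plus IL-2 replicate 1 517 and 397, and without cDKO plus IL-2 replicate 1 650 and 393. Lower regions also moved without control replicate 2 (372) or cDKO replicate 1 (374) lacking IL-2, or cDKO plus IL-2 replicate 2 (394). Peak number p-values ran from 0.286 to 0.971 for genotype and 0.429 to 0.914 for IL-2 (exact permutation).

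Passing gene lists numbered 0 with deposited lists, without chromosome 6 and with the looser call, and 2 with gene bodies plus 10 kb or a background of all listed regions, and 0 to 2 when leaving out a library. The naive and memory list had an adjusted p of 0.000206 with gene bodies plus 10 kb and 0.014 with all listed regions as background (Fisher's exact test). Its adjusted p was 0.527 with deposited lists, 0.128 without chromosome 6 and 0.626 with the looser call. With a background of regions listed in exactly 4 libraries it was 0.113, and when leaving out a library 0.00766 to 0.286 (Fisher's exact test). The TGF-beta and SMAD list passed with gene bodies plus 10 kb (0.0258) and without replicate 1 of cDKO plus IL-2 (0.00766, Fisher's exact test). It passed under no other setting run. With deposited lists 1 of 321 of its regions was lower in cDKO (odds ratio 0.6), which is no excess. Under the looser call 21 of 237 were lower (odds ratio 1.34). The Treg list passed with the wider background (0.0467) or that of regions listed in exactly 4 libraries (0.0141, Fisher's exact test). Against regions listed in exactly 4 libraries, the gene-end shares of 6.942% higher in cDKO and 4.491% higher and 3.636% lower with IL-2 no longer differed detectably. The planned background holds regions listed in all 8 libraries, which cannot be called and had 26.1% at gene ends. The cause of the changes in the gene lists was not tested.

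Replicate numbers showed little pairing of the samples: correlations of replicate differences between groups ran from -0.035 to 0.084. The highest was that of the 2 control groups. There the split by replicate number gave 3693 regions and the other mixed split 2057, so pairing in control is not excluded. With the replicate block, peak number gave p = 0.875 for genotype and 0.375 for IL-2 (exact sign flips). The genotype similarity stayed 0.0530 and 1 of 8 block splits was as large, the smallest share they allow, so the block says nothing of its stability. With deposited lists the genotype similarity was 0.0277. The shortest list limits the calls: it sets the length of all 8, and weaker regions of the longer lists are left out.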

Other observations

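The test of opposed effects and the chromosome Y comparison were chosen only after the result was seen, and the test leaving out the short list was set beforehand.

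Some regions of immune genes set a single group apart, with the examples taken by rank after their values were seen. A region 12.9 kb from Il2ra (chromosome 2, 11629633 to 11630115) was in the equal-number lists of the other 3 groups and in neither cDKO library without IL-2, though both deposited lists held it at low rank. Regions in Izumo1r, Foxp1 and Smurf1 and near Lef1 shared that pattern, and a region in Icos was in the equal-number lists of that group only, with lower peaks in 5 of the other 6 deposited lists. The equal-number lists of control plus IL-2 alone lacked regions near Ikzf2 and Dnmt3b and in Prdm1, the last of which 1 of its deposited lists held. Regions in Tet2, Lef1 and Ikzf4 were in the equal-number lists of that group only, with lower peaks in 3, 1 and 4 of the other deposited lists.

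Regions absent only from cDKO without IL-2 numbered 675 and those absent only from control plus IL-2 numbered 743, against 210 and 245 for the remaining groups and at most 449 for a pair of libraries from different groups. These groups were also the least alike (Jaccard index 0.626 to 0.663, against 0.700 to 0.726 for control without IL-2 and cDKO with it). Without the short list of control plus IL-2 replicate 2, 762 regions were absent only from cDKO without IL-2, below the highest other pair (800), while 1182 were present only there, above it (1052), so its part in the pattern cannot be told apart. A hypothesis is that IL-2 and loss of both enzymes act in opposite directions on shared regions. The distant pair gave 11540 regions and the near pair 7101, a ratio of 1.63, which restates the similarities above and does not test it.

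Chromosome Y held 0.0465% to 0.0517% of the peaks in cDKO libraries and 0.0334% to 0.0411% in control libraries (exact permutation p = 0.0286, the smallest possible, n = 4 per side), a difference picked from many columns and not adjusted. The counts were small, 45 to 57 peaks per cDKO library and 22 to 60 per control library, and did not separate the genotypes. Replicate 1 of control without IL-2, the longest list, had the 60.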
